A study of Homo sapiens with 2 samples.

How the data were processed

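Gene expression was measured in H1299 cells, an established human non-small cell lung carcinoma line that lacks p53. The cells of one sample had received a pcDNA3.1 plasmid carrying the transcription factor EGR1 and those of the other the empty pcDNA3.1 plasmid. Whether the RNA of a sample was pooled from several cultures is not known. Per the series description the cells were collected 48 hours after transfection, and per the labels' protocols biotin-labelled cRNA was made from 2 µg of total RNA and hybridised to Affymetrix arrays. Probe-set identifiers and the platform annotation supplied with the values cover 49395 probe sets. Each group held 1 array. There was therefore no replicate error, no p-value and no count of significant genes, and every difference below describes these 2 arrays and not the conditions in general.

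The deposited values are log2 probe-set levels made by the authors with RMA, per the submitters' processing notes. RMA is a standard method that corrects background, normalizes between arrays and summarises the probes of a probe set. The software, its version and settings, and the number of arrays processed together are not given in the sources used here. The 2 columns had nearly the same distribution, with quartiles of 4.28, 5.77 and 7.50 in the empty-vector array and 4.32, 5.79 and 7.47 in the EGR1 array. RMA gives no detection call and no error per probe set, and its scale is arbitrary, so levels of different probe sets were not read as relative amounts of RNA. They were compared only to choose the brightest probe set of a gene, to set the floor, to match random lists and to fit the lowess correction. In 2613 probe sets (5.29%) the values of both arrays were identical to the last digit. This was the case for 11.6% of the probe sets in the lowest decile of mean level and 0.425% in the highest decile. The number of arrays limits the precision throughout.

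Probe sets were named through the platform annotation, with symbols matched to a RefSeq gene table (assembly GRCh38.p14) by Entrez ID. Control probe sets (102) stood for no gene. Of the others, 44988 had 1 gene symbol, 1832 had several and 2473 had none here; 44961 of those with 1 symbol matched the gene table and the remainder kept the annotation's symbol. No genome build is named for the values, so no coordinates are given. A gene was represented by its brightest probe set (highest mean log2 of both arrays), which gave 18132 genes. In 198 genes several probe sets shared the highest mean level, and in 127 of these their differences were not the same; the rule fixed beforehand did not cover ties, and the order of the probe-set identifiers then decided. A floor at the 40th percentile of the mean level of all probe sets (5.22 on the log2 scale) left 12652 genes. The difference was the log2 level of the EGR1 array minus that of the empty-vector array, with no further normalization. Genes at or beyond 2-fold were counted. All 31 gene lists, the floor, the fold threshold and the rule for named genes were fixed before the data were examined. The rule named EGR1 and KRT18, the 12 genes with the largest positive and the 12 with the largest negative difference among genes past the floor whose probe sets past the floor all lay on one side of 0, and up to 4 members past the floor with the largest absolute difference in each list. Genes named outside this rule are said to be so. KRT18 was named in advance, and placed in the list of EGR1 targets, from a recollection of a paper on EGR1 and KRT18 in these cells. That paper was not given and not read here, so the recollection is unchecked and KRT18 is not independent evidence.

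Because there was no replicate, a gene list was described by its median difference over all measured members and by the percentile of that median among 10000 random lists of the same size, matched on mean level in 20 bins and drawn independently within bins. A list was said to stand apart at a percentile of 2.5 or lower or of 97.5 or higher. By chance 1.55 of 31 independent lists would do so, and the lists share members. Percentiles say how a list lay among other genes of the same 2 arrays and are not p-values. The only repeat measurement was that of several probe sets for one gene. Over 7113 genes with 2 or more probe sets past the floor, the pooled SD of the difference between probe sets of one gene was 0.15 on the log2 scale. This covers probe-level error alone, leaves out error between cultures, transfections and arrays, and may be too small where probe sets share probes. The procedure was tested on simulated data for the EGR1 comparison. Of 12652 simulated genes, all of the 100 changed by 2 log2 units were called at 2-fold, 51% of the 100 changed by exactly 1 log2 unit were called, and 0% of the 12452 unchanged genes were called. The simulated noise was the median SD between probe sets of one gene (0.09), which covers probe-level error alone and is under the pooled SD of 0.15. With noise this small all 3 shares follow from the construction, including the share near 50% at the threshold itself. They do not show how often real arrays give false calls. For the gene lists, 5% of 200 random lists with no shift stood apart and 100% of 200 lists of 30 genes shifted by 0.2 were called higher. The differences had been shuffled among genes, so the 5% follows from the construction. It does not show how often lists of related genes stand apart. The 100% follows from the construction too, since 0.2 was added to every member. That shift is above the median of most real lists that stood apart higher, so it says little about smaller shifts.

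Alternatives were the mean of all probe sets of a gene, leaving out probe sets with the suffixes _x_at and _s_at, no floor or a floor at the 60th percentile (6.38), median centring, a lowess correction of the difference on mean level (span 0.3), thresholds of 1.5-fold and 3-fold, list members past the floor only, and the mean in place of the median of a list. Matching of random lists also on genomic gene length and on the chromosome's base composition was added after the data were seen, as were EGR1 and KRT18 values per probe set, a count of genes whose probe sets share a sign, the other probe set in genes with tied probe sets, and the list of EGR1 targets without KRT18. The matching on length and chromosome was coarse, with 5 bins of mean level in place of 20, 3 length classes and 3 chromosome classes. A pseudocount had been planned for linear values only and was not needed. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.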

Results

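The study asked which genes EGR1 regulates in lung cancer cells, with apoptosis and metastasis in view, and compared H1299 cells transfected with an EGR1 plasmid with cells given the empty plasmid. EGR1 is an immediate-early zinc-finger transcription factor induced by growth factors and stress. Whole-transcriptome expression was read on 1 Affymetrix array per group, 48 hours after transfection. Of 18132 genes represented, 12652 lay above the floor on signal. Across all 49395 probe sets the values of both arrays correlated with r = 0.995 (Pearson, across probe sets, which are not independent replicates), and the median difference was 0. No difference below has a replicate check.

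The transfected gene was examined first. EGR1 had 6 probe sets, and they did not move together. Probe set 11717861_a_at was 13.3-fold higher in the EGR1 array (11.43 against 7.70 on the log2 scale), and 11751643_x_at was 6.76-fold higher (9.92 against 7.17). The other 4 were slightly lower, with log2 differences from -0.39 to -0.20. They included 11717860_a_at, the brightest, which read 10.51 in the empty-vector array and 10.12 in the EGR1 array. The spread between EGR1 probe sets (SD 1.85 over 6 probe sets) was far above the pooled SD of 0.15 between probe sets of one gene. Where each probe set lies in the transcript was not established here, and a probe set outside the plasmid's insert checks nothing about the transfection.

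**Figure D1:**
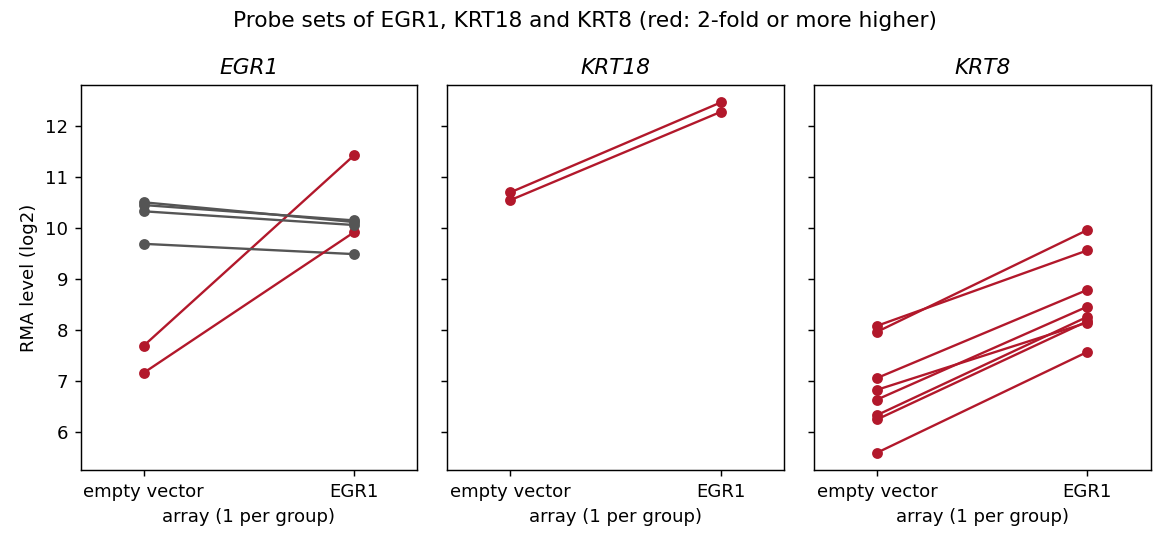
RMA level (log2, vertical axis) of every probe set of EGR1, KRT18 and KRT8 on the empty-vector array and the EGR1 array (1 array each), with a line joining the values of a probe set, red where the EGR1 array was 2-fold or more higher. In EGR1, 2 of 6 lines climb and 4 decline slightly, while both KRT18 lines and the 8 KRT8 lines climb.

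KRT18 and KRT8, the paired keratins that form the intermediate filaments of simple epithelia, were both higher in the EGR1 array. KRT18 was 3.39-fold higher by its brightest probe set (12.47 against 10.70) and 3.32-fold higher by the other. KRT8 was 3.99-fold higher by its brightest probe set, and its 8 probe sets gave log2 differences from 1.32 to 2.00 with a mean of 1.77 (SD 0.25 between probe sets). All of these KRT18 and KRT8 probe sets are of the _x_at type, which can bind similar transcripts, and both genes have many processed pseudogenes. The KRT18 pseudogene KRT18P55, named here after its values were seen, was 2.69-fold higher, from a level under the floor (4.98 in the empty-vector array). The keratins did not move as a group. Of 6 simple-epithelium keratins past the floor, 2 were at or beyond 2-fold higher and 4 were not. KRT19 was 1.18-fold higher and KRT7 1.47-fold lower, with KRT7 just under the floor in the EGR1 array (5.20). Of 9 listed keratins 7 were measured, with a median difference of 0.01 at percentile 56.7 of matched random lists. Their mean, which KRT8 and KRT18 dominate, was 0.46 and stood apart (percentile 99.96). KRT18 was named in advance from a recollection of a paper on EGR1 in H1299 cells, which was not read here, and is not independent evidence.

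At the 2-fold threshold 44 genes were higher in the EGR1 array and 1 was lower, together 0.356% of the genes past the floor. ARC, an activity-regulated cytoskeleton-associated gene of neurons, showed the largest difference at 27.2-fold (10.56 against 5.79, 1 probe set). NPTX1, a neuronal pentraxin, was 7.50-fold higher, although its lowest probe set differed by 0.18 and its level in the empty-vector array (4.77) was under the floor of 5.22. CDKN1C, which encodes the CDK inhibitor p57, was 6.38-fold higher, and its 3 probe sets ranged from 2.67 to 3.41. GDF15, a stress-induced secreted factor of the TGF-beta family, was 6.06-fold higher by its brightest probe set and differed by 0.09 in the least changed of the 4 past the floor. RRAD, a small GTPase of the RGK family, was 5.39-fold higher and SERPINA1, the alpha-1-antitrypsin gene, 4.35-fold higher, with log2 differences from 2.12 to 3.04 over the 3 probe sets past the floor and 0.33 in one under it. HEY1, a transcriptional repressor downstream of Notch, was 4.14-fold higher. The remaining genes named by rank were TMT1B at 3.85-fold, the receptor tyrosine kinase FGFR3 at 3.83-fold, SBSN at 3.65-fold and the carnitine and organic cation transporter SLC22A4 at 3.49-fold. One FGFR3 probe set differed by only 0.35. TMT1B and FGFR3 were under the floor in the empty-vector array (4.95 and 5.04), so their folds, like that of NPTX1, rest on a dim value. SBSN (5.24) and the brightest SERPINA1 probe set (5.31) lay barely above the floor in that array. The SERPINA1 probe sets 11721454_a_at (4.27) and 11721455_s_at (4.96) were under it there. The folds of SBSN and SERPINA1 therefore rest on dim values as well.

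**Figure D2:**
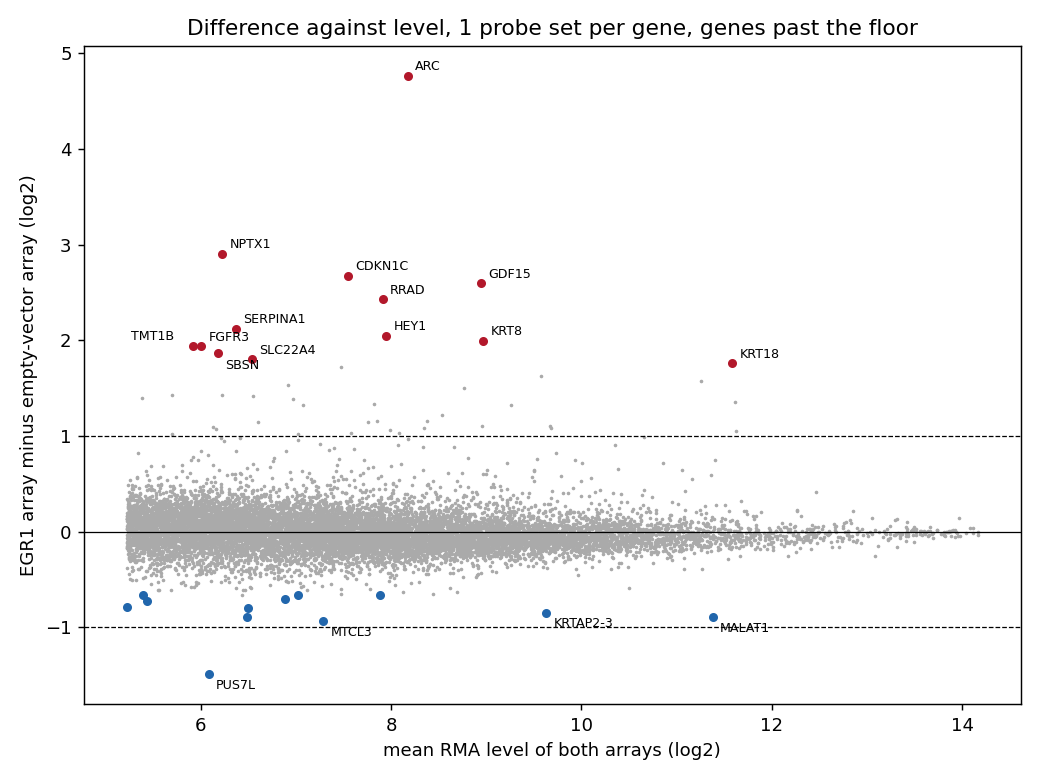
Difference between the arrays (EGR1 array minus empty-vector array, log2, vertical axis) against the mean RMA level of both arrays (log2, horizontal axis) for the 12652 genes past the floor, 1 probe set per gene. Red and blue points are the 12 highest and 12 lowest genes named by rank, with KRT18 also in red, and dashed lines mark 2-fold, with 44 points on or above the upper line and 1 below the lower line.

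Differences toward lower levels were small. PUS7L, a pseudouridine synthase family member, was the 1 gene at or beyond 2-fold lower, at 2.81-fold (5.34 against 6.83), and its other probe sets had log2 differences of -0.44 and, under the floor, -0.38. The next lowest were MTCL3 at 1.92-fold lower, the nuclear long non-coding RNA MALAT1 at 1.86-fold, ZNF283 at 1.85-fold, KRTAP2-3 at 1.80-fold, CNTLN at 1.74-fold and ZNF519 at 1.73-fold. ZNF383, TMEM156, ZNF45, ZNF90 and SLC35G1 followed at 1.65-fold to 1.58-fold lower. The direction of SLC35G1 turned without _x_at and _s_at probe sets (0.04). ZNF519, ZNF383 and ZNF90 were under the floor in the EGR1 array (4.83, 5.08 and 5.06). ZNF283, ZNF519, ZNF383, ZNF45 and ZNF90 are zinc-finger genes, so 5 of these 12 belong to that family. MALAT1 had 3 probe sets, of which the least changed had a difference of -0.04. The named probe set of KRTAP2-3 has the suffix _s_at and can bind related keratin-associated transcripts.

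Among genes with at least 2 probe sets past the floor, 28 were called at 2-fold by their brightest probe set. In 28 of these the next brightest probe set differed in the same direction, and in 16 it was at or beyond 2-fold too. Of all 44 genes called higher, 42 had no probe set past the floor on the other side of 0. The exceptions, RAPGEF3 and HES1, each had 1 or more probe sets slightly below 0 (lowest difference -0.05 and -0.03); both lie outside the rule for named genes and were chosen after their values were seen. With the mean of all probe sets the named genes FOS (0.97), GADD45B (0.77), LIF (0.77), TIMP1 (0.97) and PUS7L (-0.77) were no longer at 2-fold, and NPTX1 (1.54), GDF15 (1.88) and FGFR3 (1.14) stayed past it with smaller differences. Without _x_at and _s_at probe sets LIF (0.85) was again under 2-fold, while SERPINA1 (3.04) and NR4A1 (2.22) differed more. After the lowess correction KLF10 (1.04) reached 2-fold.

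Of the 31 lists fixed beforehand, that of immediate-early genes had the highest median. Of 29 members past the floor 3 were at or beyond 2-fold higher and 26 were not, and 22 of 30 measured members were above 0. IER3 was 2.99-fold higher, the orphan nuclear receptor NR4A1 2.83-fold, the AP-1 subunit FOS 2.15-fold and the TGF-beta-inducible factor KLF10 1.99-fold. Of the 7 NR4A1 probe sets 6 exceeded 2-fold, and the other, under the floor, differed by 0.08. The list median was 0.26 (percentile 100 of 10000 matched random lists). The middle 95% of those lists ran from -0.08 to 0.02.

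Genes known as EGR1 targets, listed from general knowledge and with KRT18 added from the recalled paper, also lay higher as a group. Of 29 measured members 20 were above 0 and 8 below, and 2 of the 26 past the floor were at or beyond 2-fold higher, KRT18 and the stress-response gene GADD45B (2.07-fold; its 4 probe sets ranged from 0.16 to 1.12). ATF3 was 1.71-fold and ID3 1.46-fold higher, and the log2 difference of ATF3 was 0.325 with the mean of all probe sets. The list median was 0.14 (percentile 100), and without KRT18 it was 0.14 (percentile 100). The EGR family and its NAB corepressors, with EGR1 at its brightest probe set, did not stand apart (6 of 7 listed measured, median 0.08, percentile 84.4). In that list NAB2, which is induced by EGR1 and represses it, was 1.38-fold higher, NAB1 differed by 0.18 and WT1 by 0.11, which became -0.07 for WT1 with the mean of all probe sets.

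Cell-cycle genes were lower by small amounts in many members. In the list of G1/S and DNA replication genes 33 of 37 members were below 0, and in that of G2/M and mitosis genes 33 of 39, but none reached 2-fold. Both medians were -0.14. The percentile was 0.01 for the G1/S list and 0 for the G2/M list, and the middle 95% of matched random lists ran from -0.10 to 0.01 and from -0.09 to -0.004. The flap endonuclease FEN1 was 1.33-fold lower, POLE2 1.28-fold, CDC6 1.21-fold, ANLN and the topoisomerase TOP2A each 1.29-fold, ECT2 1.20-fold and CDK1 1.19-fold. Cyclin E1 (CCNE1) went the other way at 1.33-fold higher. CDK inhibitors lay higher (median 0.20 over 7 members, percentile 99.98), with 1 of 7 at or beyond 2-fold. Besides CDKN1C, CDKN1B (p27) was 1.48-fold higher, CDKN2B 1.17-fold and CDKN1A (p21) 1.15-fold. When the mean of all probe sets stood for a gene, the CDK inhibitor list no longer stood apart (median 0.06, percentile 96.0).

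Apoptosis genes, which the study's question concerned, did not shift as a group. None of 31 pro-apoptotic and none of 10 anti-apoptotic genes past the floor reached 1.5-fold. The pro-apoptotic median was 0 (16 members above 0 and 16 below, percentile 74.4), and when the mean of all probe sets stood for a gene it was 0.04, just inside the upper range that counted as apart. Of the pro-apoptotic genes 34 of 37 listed were measured. The caspase CASP9 was 1.40-fold higher, whereas CASP8, HRK and the TRAIL receptor TNFRSF10A were lower by 1.47-fold, 1.37-fold and 1.35-fold. The CASP8 probe sets disagreed in sign, and without _x_at and _s_at probe sets CASP8 was 0.03. The anti-apoptotic median was -0.07 (percentile 18.8). XIAP, an inhibitor of caspases, was 1.18-fold lower and BIRC2 1.14-fold lower, while BCL2 differed by 0.12 and BAG3 by 0.10. With the mean of all probe sets BCL2 was -0.01. The p53 target list had a median of 0.03 (percentile 93.1) in this p53-null line. MDM2 was 1.29-fold lower, POLK 1.16-fold lower, ZMAT3 1.21-fold higher and RRM2B 1.18-fold higher, and MDM2 probe sets went both ways.

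Among stress lists, those of unfolded-protein and hypoxia genes lay higher, and those of heat-shock and NRF2 genes did not stand apart. In the unfolded-protein and amino-acid stress list 29 of 38 members were above 0 (median 0.06, percentile 100), with 1 at or beyond 2-fold, the pro-apoptotic transcription factor DDIT3 (CHOP) at 2.11-fold. TRIB3 was 1.40-fold and VEGFA 1.36-fold higher, and the 10 VEGFA probe sets ranged from 0.13 to 1.33. The hypoxia and glycolysis list had a median of 0.10 (25 of 32 above 0, percentile 100), and none of 31 past the floor reached 2-fold. ANGPTL4 was 1.70-fold higher, P4HA2 1.52-fold and the peptide hormone ADM 1.51-fold. The heat-shock list had a median of -0.05 (16 of 22 below 0, percentile 31.2; DNAJB4 -0.40, CHORDC1 -0.29, HSPB1 0.28). The oxidative-stress (NRF2) list had a median of -0.01 (17 of 27 below 0, percentile 62.4; HMOX1 0.43, OSGIN1 0.31, ME1 -0.20, GCLM -0.17). Type I interferon-response genes were above 0 in 36 of 42 members (median 0.17, percentile 100) without any of the 27 past the floor at 2-fold. IRF9, a subunit of the interferon-activated complex ISGF3, was 1.68-fold higher, IFI6 1.53-fold, IFI44 1.45-fold and IRF7 1.42-fold. The 4 IRF9 probe sets past the floor ranged from 0.28 to 0.75, and the 2 IFI44 probe sets past the floor differed by 0.11 and 0.53. TGF-beta and BMP response genes had a median of 0.08 (16 of 27 above 0, percentile 99.5). Of these the inhibitor of differentiation ID2 was at or beyond 2-fold (3.08-fold), JUNB was 1.87-fold higher, LTBP2 1.60-fold and SMAD7 1.49-fold. When probe sets with the suffixes _x_at and _s_at were left out, the TGF-beta list no longer stood apart (median 0.04, percentile 87.1).

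**Figure D3:**
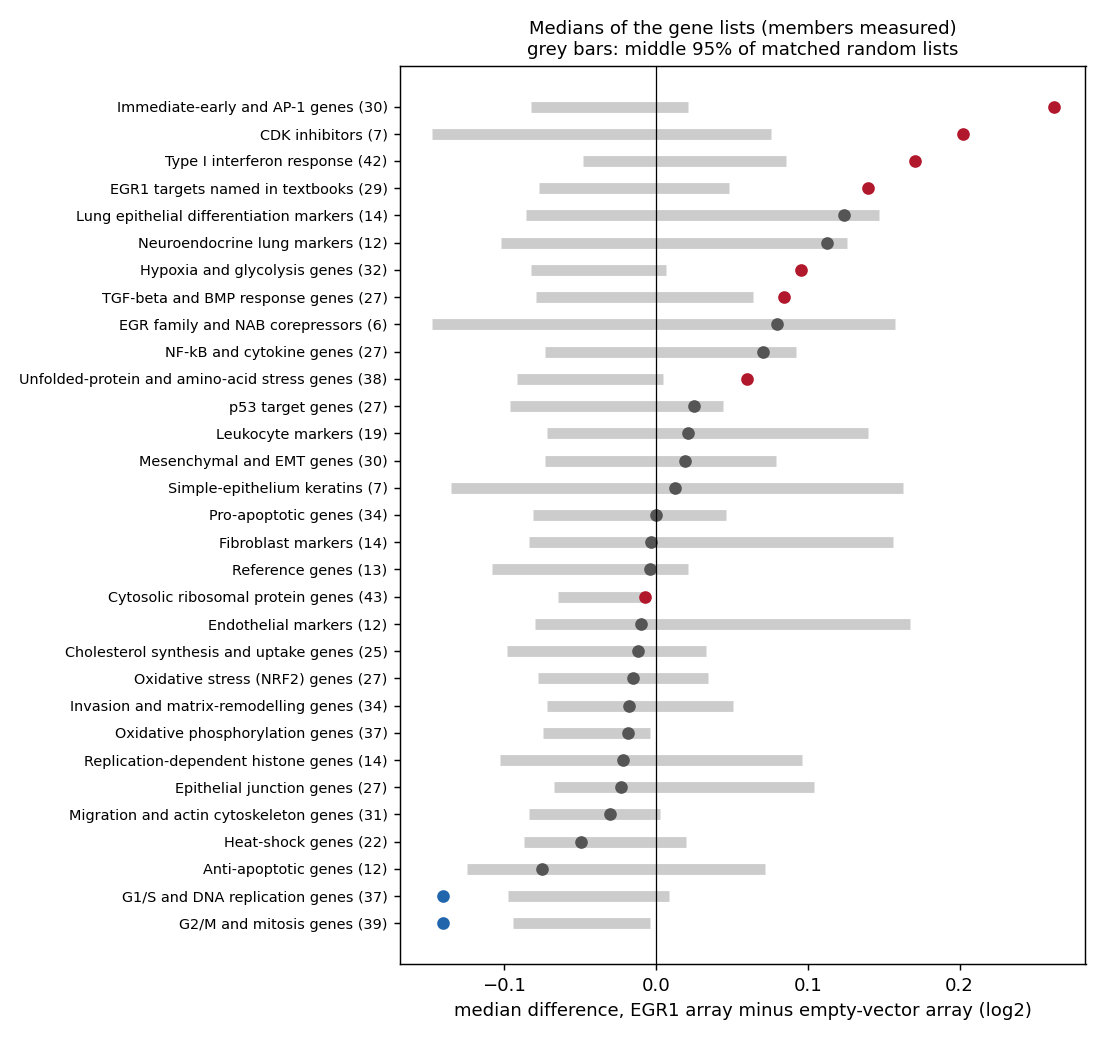
Median difference of each of the 31 gene lists (EGR1 array minus empty-vector array, log2, horizontal axis; measured members in brackets), with grey bars for the middle 95% of 10000 random lists matched on level and red points above, blue points below that range. The immediate-early list is the farthest to the right at 0.26 and the 2 cell-cycle lists the farthest to the left at -0.14.

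Lists tied to invasion and epithelial state did not stand apart. The invasion and matrix-remodelling list had a median of -0.02 (16 of 34 above 0, percentile 43.0), but 2 of 28 members past the floor were at or beyond 2-fold higher. These were the metalloproteinase inhibitor TIMP1 at 2.56-fold and the gelatinase MMP9 at 2.13-fold. The TIMP1 probe sets ranged from 0.11 to 1.43. The mean of the list was 0.09 and stood apart (percentile 98.3). The sign of its median turned when the other of 2 tied CTSD probe sets (-0.07 and 0.09) stood for that gene. The integrin ITGB4 and MMP15 were each 1.35-fold higher, and the ITGB4 probe sets went both ways. Mesenchymal genes had a median of 0.02 (percentile 70.5), with the EMT transcription factor SNAI1 1.58-fold higher, COL6A1 1.33-fold, S100A4 1.28-fold and LOX 1.22-fold, although LOX was -0.27 without _x_at and _s_at probe sets. The 6 COL6A1 probe sets past the floor ranged from 0.04 to 0.41. Restricted to members past the floor, the mesenchymal list stood apart (median 0.08, percentile 97.9). Epithelial junction genes had a median of -0.02 (percentile 15.3). JUP was 1.38-fold higher, CLDN1 1.25-fold and PRSS8 1.13-fold, whereas DSC2 was 1.23-fold lower. Migration and actin genes had a median of -0.03 (percentile 70.2), and FSCN1 (1.39-fold), MYL9 (1.25-fold), TPM2 (1.25-fold) and ACTN1 (1.22-fold) were higher. The NF-kB and cytokine list had a median of 0.07 (percentile 89.6). The cytokine LIF was 2.10-fold higher, NFKBIE 1.52-fold and ICAM1 1.46-fold, while TNFAIP3 was 1.33-fold lower. The 3 ICAM1 probe sets past the floor ranged from 0.11 to 0.54. Without _x_at and _s_at probe sets the NF-kB list stood apart (median 0.09, percentile 97.6).

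Housekeeping and metabolic lists had medians near 0. Cytosolic ribosomal protein genes had a median of -0.007, and each of 43 members lay between -0.11 and 0.10. That median was below 0 yet at percentile 98.0 of matched random lists, which ran from -0.06 to -0.009, and under 6 alternatives the list did not stand apart. RPL4 and RPS25 had differences of -0.11 and 0.10, and RPS25 probe sets went both ways. Oxidative phosphorylation genes had a median of -0.02 (percentile 89.4; COX5B 0.20, NDUFS1 -0.18), reference genes -0.004 (percentile 88.4; POLR2A 0.36, TBP -0.27), and cholesterol synthesis genes -0.01 (percentile 76.6; HSD17B7 -0.41, STARD4 0.36). The histone list had a median of -0.02 (percentile 38.1; H2BC5 0.35, H2BC6 0.28, H4C3 -0.25, H3C10 -0.25). Without _x_at and _s_at probe sets H2BC6 was -0.13 and H3C10 was 0.16. Medians this close to 0 have no settled direction. After the lowess correction those of 7 lists changed sign, namely the junction, invasion, migration, cholesterol, NRF2, oxidative phosphorylation and reference genes.

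Markers of other cell types did not differ as groups. Medians were 0.02 for leukocyte genes (percentile 42.4), -0.003 for fibroblast genes (percentile 21.4), -0.010 for endothelial genes (percentile 18.7), 0.12 for lung epithelial differentiation genes (percentile 93.8) and 0.11 for neuroendocrine genes (percentile 96.2). Of these, lung epithelial genes stood apart without _x_at and _s_at probe sets (0.19, percentile 98.8) and neuroendocrine genes by their mean (0.14, percentile 97.7). Most of the fibroblast and many of the leukocyte markers lay under the floor (2 of 14 and 8 of 19 were past it). Past the floor the largest differences in these lists were 0.30 for CD3E, 0.20 for ACTA2, 0.20 for PECAM1, 0.33 for KRT5 and 0.48 for CHGB. The CHGB probe sets past the floor ranged from 0 to 0.48. CD3E and KRT5 were under the floor in the empty-vector array, and ACTA2 was -0.003 with the mean of all probe sets and -0.02 without _x_at and _s_at probe sets. RNA integrity was alike by the control probe sets. The 3′ minus 5′ difference of ACTB was 1.94 in the empty-vector array and 1.93 in the EGR1 array, and that of GAPDH was 0.14 and 0.13. Spike-in controls read higher in the EGR1 array: the 24 poly-A spike-in probe sets by a median of 0.23 (0.06 to 0.36) and the 18 hybridisation spike-in probe sets by a median of 0.14 (0.05 to 0.24). Apart from the ribosomal list, the lists that stood apart higher had medians between 0.06 and 0.26, so the spike-in shifts were of a similar size. Background probe sets with 16 to 25 G and C bases also read higher, by 0.09 to 0.26.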

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

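Both tests of the EGR1 probe sets were chosen only after the EGR1 values had been seen. With 1 array per group none of the values below has an error.

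Of 2387 probe sets past the floor without a single gene name, 4 were at or beyond 2-fold higher and 3 lower. The higher ones were 11764032_at (log2 difference 1.62), 11716631_s_at (1.34), 11725178_at (1.06) and 11724965_at (1.01). The last is annotated to both RDH5 and a read-through transcript that includes it, and the other 3 are unnamed here. The lower ones, also unnamed here, were 11751145_a_at (-1.12), 11739033_a_at (-1.06) and 11731007_a_at (-1.03). Poly-A spike-in probe sets were higher in the EGR1 array in 24 of 24 cases (median 0.23), and hybridisation spike-in probe sets in 18 of 18 (median 0.14).

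The EGR1 probe sets disagreed, since 2 were far higher in the EGR1 array and 4 slightly lower. A swapped or wrong label is argued against by the largest difference, 3.73, which goes in the direction of the label. A candidate explanation is that the 4 other probe sets (median -0.29) lie outside the transfected sequence and read the cells' own transcript. Probe positions and the insert sequence were not used here, so this stays open. Lower transcription of the cells' own EGR1 gene also stays open, as untested.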

How the results depend on the processing

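The alternatives per EGR1 and KRT18 probe set, the count of genes whose probe sets share a sign, the other tied probe set, the list without KRT18 and the matching on gene length and chromosome were chosen after seeing the data. The 44 genes called higher became 119 at 1.5-fold and 15 at 3-fold. With the other alternatives they numbered 32 (mean of all probe sets, 28 of them among the 44), 32 (without _x_at and _s_at probe sets, 30 shared), 53 (no floor), 33 (60th-percentile floor), 44 (median-centred), 45 (lowess, 43 shared), 42 (probe sets sharing a sign) and 44 (other tied probe set). The 1 gene called lower became 29 at 1.5-fold and 0 at 3-fold, with the mean of all probe sets and with the 60th-percentile floor. EGR1 was -0.39 by its brightest probe set and reversed to 0.89 with the mean of all probe sets, to 3.73 by 11717861_a_at and to 2.76 by 11751643_x_at; 11717862_x_at gave -0.20. The reversal follows from which probe set stands for the gene. KRT18 stayed within probe-set error under each alternative run; it and KRT8 have no value without _x_at probe sets. The CDK inhibitor list stopped standing apart with the mean of all probe sets (0.057), and the TGF-beta list without _x_at and _s_at probe sets (0.0412). The ribosomal list did so with the mean of all probe sets (-0.0154), without _x_at and _s_at (-0.017), lowess (-0.0009), members past the floor (-0.0073), the mean (-0.0083) and length and chromosome matching (-0.0073). The causes were not tested. Lists that stood apart only under an alternative were the pro-apoptotic genes (mean of all probe sets, 0.0422), keratins, invasion genes and neuroendocrine markers (mean in place of median, 0.463, 0.0888 and 0.142), mesenchymal genes (members past the floor, 0.0762) and NF-kB genes and lung epithelial markers (without _x_at and _s_at, 0.088 and 0.185). Both cell-cycle lists stayed lower under each of the 8 alternatives run on lists, and 7 to 10 lists were higher. The pooled SD between probe sets was 0.180 with no floor and 0.123 with the 60th-percentile floor. Of 639 values of the other 138 named genes under alternatives, 586 moved by less than the pooled probe-set SD, 53 moved by more and 0 changed sign in a gene past 2-fold. The 138 values under median centring could not move, since the median difference was 0, and that alternative could change no count or list either. The 103 values under the 60th-percentile floor kept their probe set and could not move. Genes with 1 probe set could not move under the mean of all probe sets. In 10 genes under 2-fold 11 values changed sign, for SLC35G1, CASP8, LOX, H2BC6 and H3C10 without _x_at and _s_at probe sets, for BCL2, DDC, TIE1 and WT1 with the mean of all probe sets, and for ACTA2 with both. A pseudocount was not run, since the values are on the log2 scale. No paired analysis was possible because each group held 1 array. Dim probe sets, where ties between arrays are frequent, limit what can be seen below the floor.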

Other observations

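The groups of Notch, ID, neuronal and zinc-finger genes were chosen after their leading members had been seen, the matching on gene length and chromosome after trends with both had been seen, and the 2 tests of probe base composition after the background probe sets had been seen. Genes of the Notch pathway lay higher beyond HEY1. HES1 was 2.51-fold and HES4 2.33-fold higher, both repressors downstream of Notch, and the ligands DLL1 and JAG1 were 1.93-fold and 1.85-fold higher. The HES1 probe sets disagreed in sign. Of 27 genes past the floor 3 were at or beyond 2-fold, and the receptors differed little (NOTCH1 0.23, NOTCH2 -0.12, NOTCH3 0.17). All 4 ID genes, inhibitors of basic helix-loop-helix factors, were higher: ID2 3.08-fold, ID4 2.61-fold, ID3 1.46-fold and ID1 1.33-fold. The ID4 probe sets past the floor ranged from 0.22 to 1.40. Genes of neuronal activity and secretion beside ARC and NPTX1 included RASD1 (2.68-fold), SNAP25 (2.23-fold) and VGF (1.88-fold), while NRN1 and PLK2 had log2 differences of -0.14 and -0.20.

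As a hypothesis found in these data, whether these shifts reached beyond the genes that prompted them was tested on the other members. Without HEY1, HES1, HES4 and DLL1 the 24 other Notch genes had a median of 0.10, at percentile 99.2 of matched random lists. Without ARC, NPTX1, SNAP25, VGF, RASD1, SCG2 and CHGB the neuronal list had a median of 0.13 over 16 genes, at percentile 98.6. The genes left out were those seen before the lists were written, and JAG1 was not one of them. Both medians go with a shift wider than the leading genes in these 2 arrays, but not one shared by all members. Of the other Notch genes HES7 and LFNG were each at 0.38, while MAML1 was at -0.17 and DLL3 at -0.12. Of the other neuronal genes NPTX2, NPAS4, SYT4, PENK and RGS4 lay under the floor, and NPAS4 and SYT4 had a difference of 0. Background probe sets with 16 to 25 G and C bases were also higher, by 0.09 to 0.26, a shift of similar size and the same direction. The base composition of the probes therefore stays open here, as it does for the other lists that lay higher.

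Zinc-finger genes (symbols beginning with ZNF) were lower by small amounts. Of 339 past the floor 216 (63.7%) were below 0, against 52.8% of all genes, and the median was -0.08 (-0.07 without the 5 among the lowest named genes). The shift was larger in the 163 on chromosome 19 (median -0.154), and those on other chromosomes were not examined on their own. A trend with signal level is argued against, since after the lowess correction the median was still -0.055 (percentile 0 among matched random lists). The base composition of the chromosome as a whole is argued against as well: on chromosome 19 the 163 zinc-finger genes had a median of -0.154 and the 825 other genes 0.04. Base composition within the chromosome was not examined and stays open. The base composition of the probes stays open, because the probe sequences of the genes were not used here. The background probe sets rose with their G and C content, from between -0.07 and 0.09 at 13 or fewer such bases to 0.26 at 25, so probe sets poor in these bases could read relatively lower in the EGR1 array. A lower level of these genes in EGR1-transfected cells stays open as the biological explanation, untested.

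For the cell-cycle lists, a trend with level is argued against by the matching of random lists on level, which gave percentiles of 0.01 and 0. The percentile of at most 0.01 after the lowess correction adds little, since those random lists were matched on level too. With random lists matched on 5 bins of level, 3 length classes and 3 chromosome classes, the percentile was at most 0.01. This argues against gene length and chromosome composition only in these coarse classes, and finer differences in either stay open. The base composition of the probes stays open, because the probe sequences were not used here. The background probe set with 18 G and C bases was higher by 0.11, as part of the gradient given above. A slower cell cycle in the EGR1-transfected cells stays open as the biological explanation, untested here.

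Median differences varied between chromosomes. They were lowest on chromosomes 4 (-0.07), 13 (-0.06) and 18 (-0.05), which are poor in G and C bases, and highest on 22 (0.05), 16 (0.03) and 19 (0.02), which are rich in them. With genes ranked by genomic length, decile 1 (the shortest) had a median of 0.03 and decile 7 had the lowest, -0.05, after which the medians rose again to -0.03 in decile 10.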
